A study of Caenorhabditis elegans with 2 samples.

How the data were processed

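The series holds transcription factor ChIP-seq of HIF-1, the hypoxia-inducible factor of the nematode Caenorhabditis elegans. Per the labels, the transgenic strain OR3349 carries HIF-1 with a C-terminal GFP-FLAG tag, and tagged HIF-1 was immunoprecipitated with an antibody against GFP from sonicated chromatin. Whole larvae of mixed sex were taken at the L4 stage, 52 hours after synchronization as starved L1 larvae. The oxygen level at which the larvae were kept is not given in the sources used here. The 2 samples are biological replicates of 1 group per the labels. No control library and no other condition was analysed here, so no difference between conditions was tested.

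The authors deposited lists of regions for each replicate and for both replicates pooled, each on the genome builds ce10 and ce11. Per the file lists that accompany the samples, each list was called against a control alignment, the candidate lists hold peaks and background as input for the irreproducible discovery rate (IDR) procedure, and an optimal IDR-thresholded list was derived from both replicates. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each region is the authors' own deposited value relative to the control. It is not scaled between lists, so it was used to describe, rank and filter peaks within a list, and each replicate's signal is given separately. Between the replicate lists it was only correlated and plotted across shared peaks, and no levels were compared. The deposited −log10 q-value was the same for all IDR peaks and was not used further. The files hold no read counts, so the depth of the libraries is unknown. Confidence intervals (95%, exact Clopper-Pearson) cover counting error over peaks or genes only.

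Positions are those of the ce11 lists, which matches the WBcel235 assembly. Genes, transcripts and non-coding RNA genes were taken from Ensembl release 115, and 19973 protein-coding genes on the nuclear chromosomes with 29784 transcript starts were used. The ce10 lists were used for numbers of regions and their signal and, as an alternative, for the agreement of the replicates within that build. A promoter window ran from 1000 bp upstream to 200 bp downstream of a transcript start. An IDR peak counted as found in a replicate when a candidate region of that replicate had its summit within 100 bp, and the expected share came from 100 circular shifts of all summits along their chromosomes. Promoter shares and shares of non-coding RNA genes with a summit within 250 bp were compared with 1000 such shifts (permutation test, one-sided), for which 0.001 is the smallest possible p.

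The core of the hypoxia response element, RCGTG on either strand, was searched within 50 bp of each summit and in windows of the same width centred 500 bp to the left and right (exact McNemar test, two-sided). The share was compared between the strongest and the weakest 353 peaks by Fisher's exact test. All 2080 strand-merged 6-mers were compared between summits and both flanks by Fisher's exact test with Benjamini-Hochberg adjustment. For 23 gene lists, the share of members with a summit in their promoter window was compared with that of all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. An adjusted p below 0.05 was called. Over all lists, 9 of the names matched no protein-coding gene of the annotation. Some genes are members of more than 1 list, so the lists are not separate evidence. Peaks per chromosome were compared with chromosome length and number of genes by binomial tests. These tests treat peaks and genes as independent, which neighbouring peaks and genes that share a promoter are not: 585 of the 2010 promoter peaks lay in the windows of more than 1 gene.

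The lists, tests, windows and most alternatives were fixed before the data were examined. Genes were named by a fixed rule: those at the 20 strongest IDR peaks (by promoter window, otherwise the nearest gene), up to 4 members of each list with the highest signal, every member of the lists of HIF-1 pathway components and of reported HIF-1-dependent hypoxia genes, and the 5 6-mers with the smallest adjusted p. Alternatives were the 1765 strongest IDR peaks, the 3531 strongest candidate regions of one replicate alone, other windows and distances, other backgrounds, and 7-mers. Alternatives to the shift tests used 200 shifts. Leaving out the 176 peaks near tRNA genes and comparing strong with weak peaks by 6-mer were chosen after seeing the data. The code of the comparisons was checked on simulated data. At 3531 random positions no 6-mer was called and the RCGTG fold over the flanks was 1.04. Random positions lack the difference in composition between the real summits and their flanks, so they do not test the comparisons for it. Of 100 random gene lists, 0 were called. An element planted in 200 windows was recovered in 200 and ranked 1, and 100 of 100 planted lists were called. The planted elements and lists were made to be found, so they test the code only. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.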

Results

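HIF-1 binding was mapped by ChIP-seq against the GFP tag in 2 biological replicates of whole L4 larvae. The optimal IDR list held 3531 peaks on ce11 with a median signal of 158 and a range of 95.1 to 7830. These were the 3531 strongest of the 30000 pooled candidate regions. In 64 cases, an IDR region repeated the interval of another region with a different summit. Each replicate had its own list of 30000 candidate regions.

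The first question was whether both replicates held the same peaks. Of the 3531 IDR peaks, 3393 were found in both replicate lists, 96.1% with a 95% interval of 95.4% to 96.7%, whereas random shifts of the summits gave 2.1%. Replicate 1 held 3434 of them (97.3%) and replicate 2 held 3488 (98.8%). The candidate lists include background regions and are therefore permissive. Among only the 3531 strongest regions of each replicate, 2464 of the IDR peaks (69.8%) were found in both. All of the 353 strongest IDR peaks were found in both replicate lists, against 318 of the 353 weakest (90.1%, 95% interval 86.5% to 93.0%). Across the 3393 shared peaks, the signal of the replicates had a Spearman correlation of 0.726 and a Pearson correlation of 0.808 on the log2 scale. Peaks are not independent replicates, the IDR list was itself derived from both replicates, and no p is given for these correlations.

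**Figure D1:**
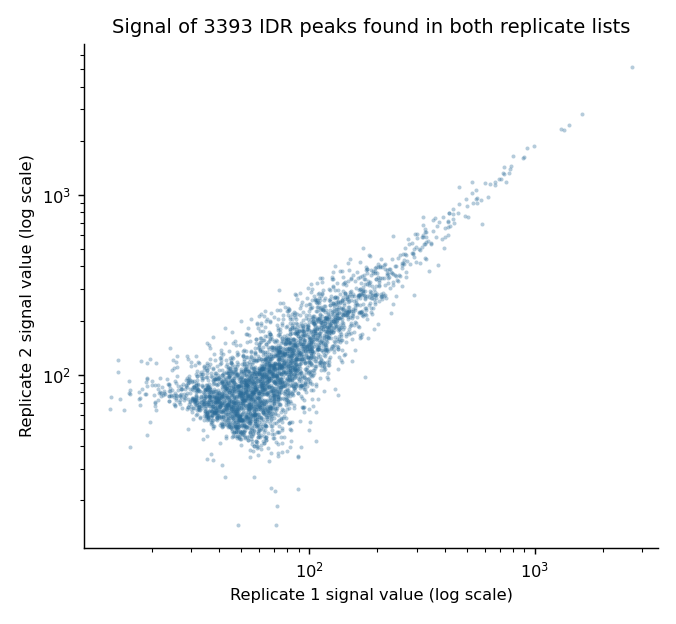
Signal value of replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale) for the 3393 IDR peaks found in both lists, 1 point per peak. The strongest peak, upstream of egl-9, lies at 2707 and 5147, and the scatter widens toward low signal.

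The strongest peak of the genome lay upstream of egl-9, the prolyl hydroxylase that marks HIF-1 for degradation (V:10466293-10467557, signal 7830). Its summit was intergenic, 1747 bp upstream of the nearest egl-9 start, outside the promoter window, and it ranked 1 in both replicates (signal 2707 and 5147). The second lay 200 bp upstream of nhr-57, a nuclear hormone receptor gene used as a reporter of HIF-1 activity (V:4131109-4132139, signal 4447), and ranked 2 in both. The peak of pck-1, which encodes phosphoenolpyruvate carboxykinase, had a signal of 3614 and a summit 992 bp upstream of the start (III:66875-67598). The peak nearest tpi-1, triosephosphate isomerase, had a signal of 2516 (II:12040053-12040701), sdha-1, the flavoprotein subunit of succinate dehydrogenase, 2472 (X:8545921-8546489), pccb-1, a propionyl-CoA carboxylase subunit, 2146, and mdh-1, malate dehydrogenase, 1818. The mdh-1 peak also lay in the promoter window of F46E10.3.

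Also among the 20 strongest, an intronic peak in hlh-30, the TFEB orthologue, had a signal of 2837 (IV:4025800-4026477) and an intronic peak in skn-1, the Nrf orthologue, 2142 (IV:5655886-5656526). The peak shared by the promoter windows of jmjd-1.2, a JmjC histone demethylase gene, and F29B9.11 had a signal of 1926, and the peak nearest jmjd-2 had 1905 with its summit 1055 bp upstream. The peak of mai-1, a homologue of the mitochondrial ATPase inhibitor, lay in its 5' UTR with a signal of 3627. The remaining peaks of the 20 lay in introns of Y62E10A.13 (3850), ZK470.2 (2694) and H18N23.2 (2443), in the promoter windows of Y59A8B.24 (2229), taap-1 (2086), rhy-1 (2031) and the pair T18D3.1 and T18D3.9 (2033), and nearest K01H12.4 (1921). Each of the 20 was found in both replicates. The nearest gene is a position only, since target genes were not measured.

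Among the 15 reported HIF-1-dependent hypoxia genes, 11 had an IDR peak in their promoter window (73.3%, 95% interval 44.9% to 92.2%), against 2416 of the 19958 other protein-coding genes. The odds ratio was 19.97 (Fisher's exact test, adjusted p = 3.39e-07). It was 5.52 (adjusted exact p = 0.0214) against the 6026 genes with a candidate region in both replicates, 8.25 (7 of 15) with a promoter window of 500 bp and 35.3 (13 of 15) with one of 2000 bp, and over 9 alternatives the adjusted p ran from 1.12e-08 to 0.0214. Besides nhr-57, they included rhy-1, a regulator acting upstream of egl-9 (signal 2031, II:9160087-9160909), and sqrd-1, the sulfide:quinone oxidoreductase (1789, IV:14219571-14220144). F22B5.4 followed with 1253, the promoter-window peak of egl-9 with 981 and cdo-1, cysteine dioxygenase, with 521. Signals were 448 at ethe-1, a sulfur dioxygenase gene, 382 at smf-3, a metal transporter gene, and 303 at cysl-2. The weakest were 225 at ftn-1, a ferritin gene, and 102 at phy-2, a prolyl 4-hydroxylase gene. RCGTG lay within 50 bp of the summit at 11 of the 13 promoter peaks of this list. No promoter peak was found at fmo-2, ftn-2, suox-1 and dct-1. Of these, fmo-2 had 0 IDR summits within 5000 bp of the gene, ftn-2 had 2, suox-1 had 2 and dct-1 had 3.

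Of the 11 HIF-1 pathway components, 4 had a promoter peak: rhy-1, egl-9, hif-1 (221) and aha-1, the partner of HIF-1 (162). The share of 36.4% was not past the threshold (odds ratio 4.14, adjusted exact p = 0.0680), and RCGTG lay at 3 of the 6 peaks. The list passed with the 1765 strongest peaks (odds ratio 7.49, adjusted exact p = 0.0161), without replicate 1 (5.87, adjusted p = 0.0166), with a window of 2000 bp (6.50, adjusted p = 0.00680) and with genes that share a peak counted once (5.49, adjusted p = 0.0319). It did not pass without replicate 2 (4.35, adjusted exact p = 0.0543), against genes with a candidate region in both replicates (3.002, adjusted p = 0.325), within classes of promoter GC (3.54, permutation test, adjusted p = 0.145) or with a window of 500 bp (2 of 11, 2.09, adjusted p = 0.399), and over 9 alternatives the adjusted p ran from 0.00680 to 0.399. Promoter peaks were not found at vhl-1, cul-2, elb-1, elc-1, rbx-1, cysl-1 and swan-1, and vhl-1, elb-1 and rbx-1 had 0 summits within 5000 bp. The egl-9 gene (V:10468517-10476915) had 11 IDR summits within 5000 bp, 9 of them with RCGTG within 50 bp. The hif-1 gene (V:20780407-20785260) had 6, with a highest signal of 772 and RCGTG at 1. The strain carries tagged hif-1 sequence in a copy number not given in the sources used here, and reads from it would map to this locus.

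**Figure D2:**
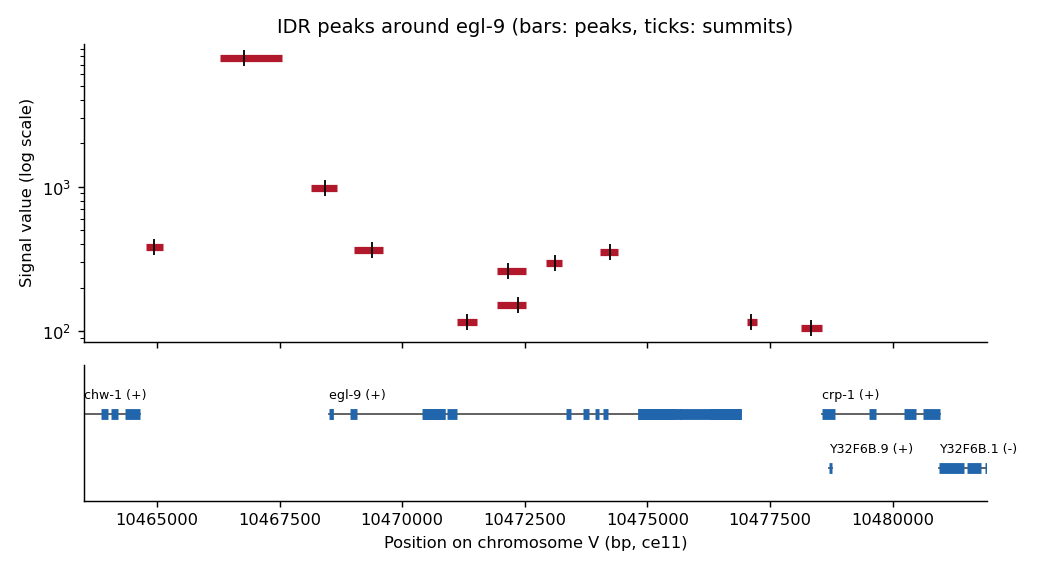
IDR peaks (red bars, black ticks at summits) by position on chromosome V and signal value (log scale) around egl-9, with exons in blue and strand in parentheses. The peak of signal 7830 lies upstream of the gene, and 11 summits fall within 5000 bp of it.

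Promoter peaks at further pathways were examined with lists fixed beforehand. No ChIP-seq of another protein was analysed, so HIF-1 binding at these lists could not be told apart from signal shared with other factors. For comparison, RCGTG lay at 42.4% of all IDR peaks in promoter windows. Of 27 genes of glycolysis and gluconeogenesis, 15 had a promoter peak (55.6%, odds ratio 9.09, adjusted exact p = 3.39e-07), with pck-1, gpi-1 (1567), aldo-1 (1434) and ldh-1 (1415) the strongest. RCGTG lay at 11 of their 16 peaks. Of 36 electron transport chain genes, 20 had one (55.6%, odds ratio 9.10, adjusted exact p = 3.67e-09). The strongest were sdha-1, mev-1 (1794, III:10333948-10334442) and sdhd-1 (891), all encoding succinate dehydrogenase subunits, and coq-2 (693), of ubiquinone synthesis, with RCGTG at 10 of 20 peaks. Of 25 heat shock proteins and chaperones, 13 had one (52.0%, odds ratio 7.87, adjusted exact p = 5.03e-06), led by hsp-1 (691), hsp-90 (560), bag-1 (531) and hsp-60 (477), with RCGTG at 6 of 16 peaks. Against the genes with a candidate region in both replicates, the odds ratios were lower, at 5.65 for glycolysis, 3.77 for electron transport and 3.91 for heat shock (adjusted exact p = 0.00490, 0.00490 and 0.0268, the highest of 9 alternatives for each). The lowest of the 9 were 9.28e-12, 3.70e-11 and 3.08e-07, and the odds ratio of glycolysis rose to 19.1 with a window of 2000 bp (21 of 27).

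Cytosolic ribosomal protein genes had a high share of promoter peaks. A promoter peak was present at 63 of 78 (80.8%, 95% interval 70.3% to 88.8%, odds ratio 31.1, adjusted exact p = 8.18e-43). This share was the highest of the 23 lists, but the reported hypoxia genes were higher with the 1765 strongest peaks (66.7% against 64.1%) and with a window of 2000 bp (86.7% against 83.3%). Against genes with a candidate region in both replicates, the odds ratio was 11.9 (62 of 70, compared with 39.4% of other genes, adjusted exact p = 5.76e-16). Over 9 alternatives the adjusted p ran from 1.75e-46 to 6.57e-05. The highest came from 100000 permutations within classes of promoter GC and was the smallest value that their number allowed. The strongest were rpl-3 (1257), rpl-15 (914), rps-23 (733) and rpl-35 (660), and the list's peaks had a median signal of 244. RCGTG lay at 24 of the 61 peaks of the list (39.3%), compared with 42.5% of the other IDR peaks in promoter windows (Fisher's exact test, p = 0.694).

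A further 3 lists were enriched, with larger adjusted p than the other enriched lists. Members with a peak that were also among the reported hypoxia genes were smf-3 and ftn-1 (iron) and phy-2 (prolyl hydroxylases). Iron and heme genes had promoter peaks at 8 of 21 (odds ratio 4.46, adjusted exact p = 0.00508), with mfn-1 (441), smf-3, iscu-1 (233) and aco-2 (227) the strongest and RCGTG at 5 of 9 peaks. Prolyl hydroxylases and collagen processing genes had them at 7 of 15 (odds ratio 6.34, adjusted exact p = 0.00262), led by pdi-2 (1141), a subunit shared with prolyl 4-hydroxylase, then pdi-3 (308), bli-4 (144) and pdi-1 (141), with RCGTG at 4 of 7 peaks. Autophagy and mitophagy genes had them at 11 of 29 (odds ratio 4.43, adjusted exact p = 0.00102), led by hlh-30 (480), lgg-2 (256), lgg-1 (243) and atg-9 (181). RCGTG lay at 4 of the 15 peaks of the autophagy list (26.7%), and the odds ratio of this list was 7.70 with a window of 2000 bp. When the background was limited to the 6026 genes with a candidate region in both replicates, these lists no longer passed, with odds ratios of 2.00, 2.63 and 1.65 and adjusted p of 0.350, 0.229 and 0.350. Over 9 alternatives, the adjusted p ran from 0.000950 to 0.350 for the iron list, from 0.000552 to 0.369 for the prolyl hydroxylase list and from 4.71e-07 to 0.350 for the autophagy list. The prolyl hydroxylase list also lost its call with the 1765 strongest peaks (adjusted exact p = 0.369), and the iron list with a promoter window of 500 bp (adjusted p = 0.0947).

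Peaks were rare at 2 lists. Serpentine chemoreceptor genes, a large sensory family, had promoter peaks at 11 of 1290 (0.853%, odds ratio 0.0579, adjusted exact p = 9.68e-57), and collagen genes at 3 of 176 (1.70%, odds ratio 0.124, adjusted p = 2.31e-06). The strongest were srh-2 (373), srh-17 (253), srh-269 (228) and sre-23 (221), and col-71 (336), col-38 (271) and col-185 (160). The peaks of srh-269 and col-185 lay within 250 bp of a tRNA gene. RCGTG lay at 5 of the 12 chemoreceptor peaks and 0 of the 3 collagen peaks. Against the 6026 genes with a candidate region in both replicates, the chemoreceptors no longer passed (odds ratio 0.686, adjusted exact p = 0.469). That background leaves out genes without a candidate region, so it cannot test how rare such regions are in this family. The odds ratio of the chemoreceptors was 0.0997 with a window of 2000 bp, and over 9 alternatives the adjusted p ran from 1.15e-62 to 0.469. The odds ratio of the collagens was 0.225 with the 1765 strongest peaks and 0.221 without replicate 2 (adjusted exact p = 0.00888 and 0.000145), within a range over 9 alternatives of 2.98e-08 to 0.00888.

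The other lists did not pass with all IDR peaks and the windows set beforehand. Sulfide and cysteine metabolism had 5 of 25 (adjusted exact p = 0.285), oxidative stress and glutathione genes 5 of 27 (adjusted p = 0.423), histones 6 of 50 (adjusted p = 1) and nuclear hormone receptors 26 of 269 (adjusted p = 0.285), among them nhr-40 (954) and nhr-135 (547). RCGTG lay at 5 of 5, 3 of 5, 0 of 4 and 13 of 29 of their peaks. The sulfide genes with a peak included sqrd-1, cdo-1, ethe-1 and cysl-2, already counted among the reported hypoxia genes. Cytochromes P450 had 3 of 74 (odds ratio 0.305, adjusted exact p = 0.0644), with RCGTG at 0 of 2 peaks, and UDP-glycosyltransferases 4 of 67 (0.458, adjusted p = 0.195), with RCGTG at 1 of 4. The P450 list passed as depleted with the 1765 strongest peaks (0 of 74, adjusted exact p = 0.0254), without replicate 1 (odds ratio 0.296, adjusted p = 0.0417) and without replicate 2 (1 of 74, odds ratio 0.104, adjusted p = 0.00404), with a range over 9 alternatives of 0.00404 to 0.200. The UDP-glycosyltransferase list passed as depleted with a window of 2000 bp (odds ratio 0.343, adjusted exact p = 0.0483, range 0.0483 to 0.796). Markers of tissues in the whole larva had few peaks: intestine 1 of 25 (adjusted exact p = 0.423), hypodermis 0 of 21 (adjusted p = 0.154), muscle 2 of 27 (adjusted p = 0.800), neurons 3 of 36 (adjusted p = 0.675) and germline 3 of 67 (odds ratio 0.338, adjusted p = 0.104). The germline list passed as depleted without replicate 2 (odds ratio 0.233, adjusted exact p = 0.0403), with a window of 2000 bp (0.253, adjusted p = 0.0194) and in a permutation test within classes of promoter GC (0.263, adjusted p = 0.0241), and over 9 alternatives the adjusted p ran from 0.0194 to 0.807. RCGTG lay at 1 of 1 intestine, 1 of 2 muscle, 2 of 3 neuron and 2 of 3 germline peaks. Innexins had 0 of 25 (adjusted exact p = 0.107). With lists of this size, a count of 0 does not exclude peaks, and the 95% interval reached 13.7% for innexins. Without replicate 2, innexins and intestine markers each had 2 of 25 (odds ratio 0.661, from 0 and 0.301), muscle markers 4 of 27 (1.32, from 0.578) and UDP-glycosyltransferases 6 of 67 (0.747), and without replicate 1 neuron markers had 6 of 36 (1.41, from 0.657). None of these passed (adjusted exact p from 0.487 to 0.796).

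**Figure D3:**
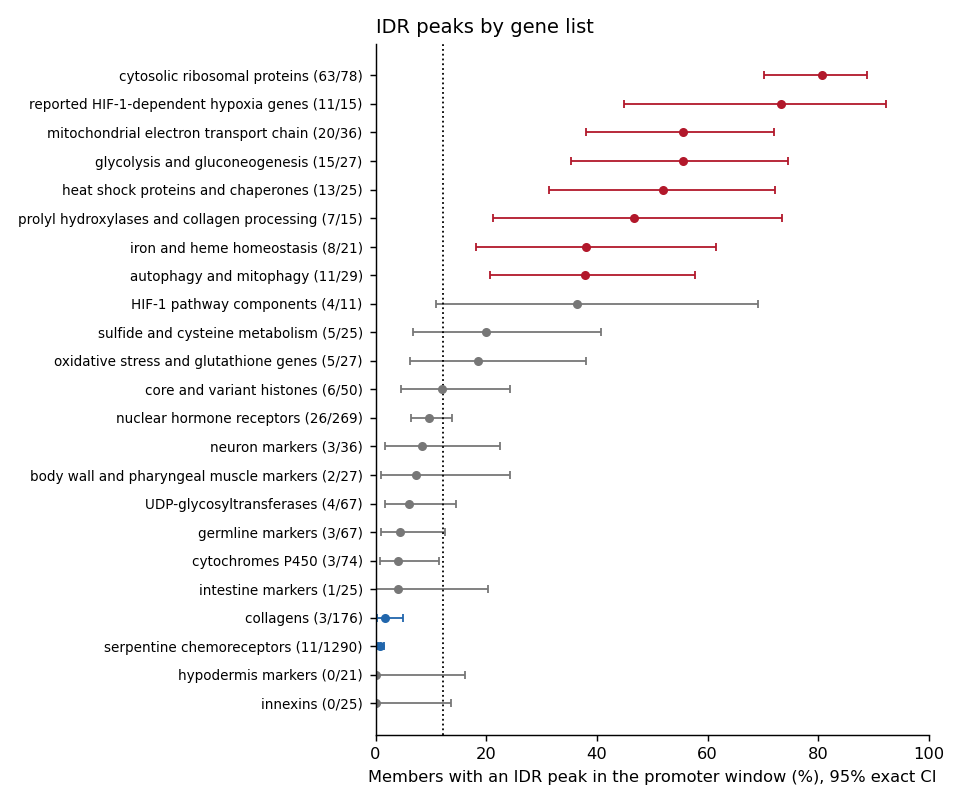
Share of each list's members with an IDR peak in the promoter window (points) with 95% exact intervals (bars) and counts in parentheses. Red lists were enriched and blue lists depleted at adjusted p below 0.05, grey lists passed neither, and the dotted line marks all protein-coding genes, 2427 of 19973.

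Peaks lay mainly near gene starts. A promoter window held 2010 summits (56.9%, 95% interval 55.3% to 58.6%), compared with 25.8% ± 0.764 (SD, 1000 shifts) at random, and no shift exceeded 28.2% (permutation test, p = 0.001, the smallest possible). By annotation of protein-coding genes alone, 2440 summits were intergenic (69.1%), 832 intronic (23.6%), 120 in 5' UTRs, 83 in coding exons and 50 in 3' UTRs. A summit in a non-coding RNA gene between protein-coding genes thus counted as intergenic. Chromosome X held 731 peaks, 1.17 times the number given by its length (exact binomial test, adjusted p = 5.34e-06) and 1.51 times that given by its genes (adjusted p = 7.09e-30). Chromosomes III (1.21 times, adjusted exact p = 4.10e-06), I (1.1 times, adjusted p = 0.0183) and II (1.08 times, adjusted p = 0.0371) were also above their length, and V (0.729, adjusted p = 6.13e-17) and IV (0.830, adjusted p = 4.10e-06) were below. By number of genes, III (1.26 times) and I (1.15 times) were above as well (adjusted exact p = 1.82e-08 and 0.000699), but II stood at 0.956 times (adjusted p = 0.238). Without the 176 peaks near tRNA genes, the ratio for X was 1.11 (adjusted exact p = 0.00362).

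Non-coding RNA genes were examined because genes of RNA polymerase III give shared signal in many ChIP-seq experiments. A summit lay within 250 bp of 188 of the 612 tRNA genes (30.7%), compared with 2.07% after shifts (permutation test, p = 0.001, the smallest possible). These 176 peaks were 4.98% of all IDR peaks and had a median signal of 144, with a highest of 351. Shares were 22.3% for snoRNA genes (77 of 346), 11.6% for snRNA genes (15 of 129) and 5.75% for miRNA genes (15 of 261, permutation test, adjusted p = 0.00499), and 0 of 20 rRNA genes had a peak. With the 1765 strongest peaks, miRNA genes no longer passed (permutation test, p = 0.129).

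The next question was whether the peaks held the sequence bound by HIF-1 and its ARNT partner. RCGTG lay within 50 bp of 1488 of the 3531 summits (42.1%, 95% interval 40.5% to 43.8%), compared with 14.98% in the left and 14.2% in the right flank. The share was 2.89 times the mean of the flanks (exact McNemar test, p = 6.17e-142 and 7.17e-150). The flanks are not matched in base composition: AAAATT, rich in A and T, lay at 16.8% of summits and 43.8% of flanks. The fold was not adjusted for this difference, so it does not measure the element alone. Of the promoter candidate regions outside the IDR list, 21.8% held it, compared with 42.4% of IDR promoter peaks (odds ratio 2.65, Fisher's exact test, p = 2.82e-74). RCGTG went with peak strength: it lay at 61.8% of the 353 strongest peaks and 37.4% of the 353 weakest (odds ratio 2.70, Fisher's exact test, p = 1.28e-10). From the strongest to the weakest group of about 353 peaks, the share fell from 61.8% to 35.4% in group 7 and was 37.3% in group 10. Base composition differed with strength as well: AAAAAA lay at 18.4% of the strongest 882 peaks and 26.8% of the weakest 882. Neither the comparison by strength nor that with candidate regions was adjusted for base composition, so they do not measure the element alone.

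**Figure D4:**
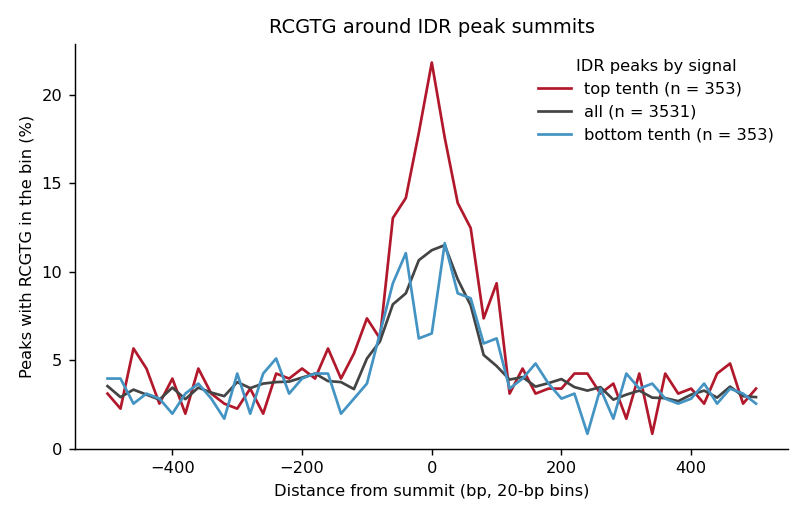
Share of peaks with RCGTG in 20-bp bins by distance from the summit (bp), for all 3531 IDR peaks and for the 353 strongest and 353 weakest by signal. At the summit, 21.8% of the strongest, 11.2% of all and 6.52% of the weakest peaks held RCGTG in the bin. In the bin centred 20 bp to the right, the shares were 17.6%, 11.5% and 11.6%.

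A search free of the assumed element found many sequences. Of the 6-mers tested, 843 were more frequent at summits than in flanks and 625 less frequent. The smallest adjusted p belonged to GAGAGA, at 24.8% of summits and 4.89% of flanks (odds ratio 6.41, adjusted exact p = 5.57e-185). AGAGAG was also higher (21.2% and 4.18%), and the A and T rich AAAATT (16.8% and 43.8%), AAAAAT (23.8% and 50.4%) and TTAAAA (7.93% and 28.2%) were lower. All 16 6-mers that hold RCGTG were among the 843 higher ones. The best was ACGTGC, rank 23 among the higher 6-mers, at 8.55% of summits and 1.39% of flanks (odds ratio 6.65, adjusted exact p = 1.19e-67). These 16 hold the element already tested above, so they are not separate evidence for it. The comparison of 6-mers was not adjusted for base composition either, so it does not measure the element alone.

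On ce10, the same data gave 3577 IDR peaks, 46 more than on ce11 (1.3%), with signal from 93.8 to 7820. On both builds the IDR list consisted of the strongest pooled candidate regions. No positions were compared between builds.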

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

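Comparisons of strong with weak peaks by 6-mer and those without the peaks near tRNA genes were chosen after the results were seen. The promoter share, the RCGTG share and its dependence on strength, the X ratio and the tRNA share kept their direction and side of the threshold under all alternatives run for each. The share of IDR peaks found in both replicates was 82.2% within 50 bp, 99.2% within 200 bp and 75.2% by reciprocal overlap, which change the matching rule, and 98.5% with the strongest 1765 peaks and 69.8% among the top regions of each replicate, which change the peaks or regions compared. The signal correlation moved to 0.757 within 50 bp, 0.690 by reciprocal overlap and 0.789 among the top regions. With 7-mers, of which 8192 were tested, 2229 were higher and 1538 lower. A different comparison, of the strongest with the weakest 882 peaks, gave 39 6-mers higher and 14 lower; why these were fewer was not tested. Against genes with a candidate region in both replicates, 5 lists were enriched and 1 depleted; fewer genes were tested, and the odds ratios of the lists that lost their call also moved toward 1. Depleted lists numbered 4 with a promoter window of 2000 bp, and 3 to 4 when either replicate was left out, 4 without replicate 2; the cause was not tested. Of lists never called, several changed direction, and the cause was not tested. The odds ratio of oxidative stress genes turned to 0.503 with the strongest peaks and 0.833 against candidate genes. That of histones, 0.986 at first, turned to 1.14 with the strongest peaks, 1.24 to 1.34 with one replicate left out, 1.01 without the tRNA peaks, 1.28 with 500 bp and 1.19 with 2000 bp. Nuclear hormone receptors turned to 1.03 with shared peaks counted once, muscle markers, 0.578 at first, stood at 0.562 without replicate 1 and turned to 1.32 without replicate 2, and neuron markers, 0.657 at first, stood at 0.95 without replicate 2 and turned to 1.41 without replicate 1 and 1.08 at 2000 bp. Of 87 named genes with a promoter peak, 68 kept one among the strongest 1765 peaks, 86 without replicate 1 and 81 without replicate 2. Without the peaks near tRNA genes 85 kept one, and srh-269 and col-185 lost theirs. With a window of 500 bp 66 kept one, and pck-1, rhy-1, skn-1 and mdh-1 were among those lost. Of lists not called at first, HIF-1 pathway components passed under 4 alternatives, cytochromes P450 and germline markers under 3 each and UDP-glycosyltransferases under 1. Iron and prolyl hydroxylase genes lost their call under 2 each, and autophagy genes, chemoreceptors and miRNA genes under 1 each; the cause was not tested. No paired analysis was possible because the series has 1 group. Depth is unknown, so it was not assessed whether more reads would add peaks.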

Other observations

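The families, the 6-mers by strength, the tests of RCGTG at ribosomal protein promoters, of candidate regions on X and of JmjC genes were chosen only after results were seen. The comparison within classes of promoter GC had been planned for all lists, and was put to the question of ribosomal protein genes afterwards. Among 175 families of at least 10 protein-coding genes that share a name stem, 17 had promoter peaks more often than other genes and 16 less often (Fisher's exact test, adjusted p below 0.05). Outside the fixed lists, apart from the neuron marker rab-3, they included proteasome subunit genes (rpn, 8 of 13, odds ratio 11.6, adjusted exact p = 0.000667; rpn-6.1 at signal 838), Rab GTPase genes (rab, 10 of 20, odds ratio 7.26, adjusted p = 0.000700; rab-7 at 561), secretory pathway genes (sec, 9 of 19, odds ratio 6.53, adjusted p = 0.00228) and translation initiation factor genes (eif, 10 of 25, odds ratio 4.84, adjusted p = 0.00464). Vacuolar ATPase genes (vha) had 8 of 20 and genes of the large mitochondrial ribosomal subunit (mrpl) 13 of 41 (adjusted exact p = 0.0108 and 0.00661). Genes of the small subunit (mrps) had 4 of 29 (odds ratio 1.16, adjusted exact p = 0.868), and the 2 subunits were not tested against each other. Peaks were rare at C-type lectin genes (clec, 3 of 240, odds ratio 0.0904, adjusted exact p = 1.77e-08), F-box genes (fbxa, 7 of 170, adjusted p = 0.00582) and neuropeptide-like genes (nlp, 1 of 71, adjusted p = 0.0115). The counts of 17 and 16 partly repeat the fixed lists: rpl and rps were among the 17, and most of the 16 were chemoreceptor stems or col. A stem is only a name. The stems lin (19 of 47) and tag (15 of 57), counted among the 17, need not be families of related genes.

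Between the strongest and weakest 882 peaks, CGTGCA had the smallest p, at 12.5% and 4.2% (adjusted exact p = 5.29e-07), and ACGTGC, which holds RCGTG, stood at 14.7% and 6.46% (adjusted p = 9.28e-06). CGGCCA (11.2% and 3.85%), CTAGGC (9.41% and 2.83%) and GGCCTA (9.64% and 3.17%) were also more frequent in strong peaks (adjusted exact p = 4.25e-06, 4.75e-06 and 1.15e-05).

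No biological explanation was tested for the patterns that follow, since the series has 1 group. Ribosomal protein genes had promoter peaks at 80.8% of members. Overall promoter GC content as the whole cause is argued against, since within 5 classes of promoter GC the odds ratio was 23.7. These classes cover the whole promoter window and do not control local base composition at the summits. Signal at promoters without the element stays open: RCGTG was more frequent at these peaks than at promoter candidate regions outside the IDR list (39.3% and 21.8%, odds ratio 2.33, Fisher's exact test, p = 0.00265), but against their own flanks the excess passed on the right (16%, p = 0.0125) and not on the left (21.3%, p = 0.0708).

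Of the tRNA genes, 30.7% had a peak. Reads shared between identical copies are a candidate explanation: 28 of 143 genes of unique sequence had a peak (19.6%) and 160 of 469 with an identical copy (34.1%), an odds ratio of 0.470 (Fisher's exact test, p = 0.000889). Other differences between unique and copied genes were not tested, and unique genes too had a share above the 2.07% after shifts. Whether the signal goes without the element could not be decided, with RCGTG at 37.5% of tRNA peaks and 42.4% of other peaks (odds ratio 0.816, exact p = 0.211).

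Chromosome X held more peaks than its length gives (1.17 times), as did I, II and III, with III at 1.21 times. The chromosomes share a common total, so the low counts on V (0.729 times) and IV (0.830 times) raise the other ratios. An excess by length particular to X was therefore not shown. Peaks at tRNA genes are argued against as the whole cause of the X ratio. Of the 3355 other peaks, 661 lay on X, 1.11 times the number by length (binomial test, exact p = 0.00241). A general surplus of candidate regions is argued against as well, since X held 5222 of 30000 (0.985 times). RCGTG was 1.03 times as dense on X as on the autosomes, against 1.22 times for peaks, which leaves open that it may add a part. The autosomes here include V and IV. RCGTG lay at 46.2% of X peaks and 41.1% of autosomal peaks (odds ratio 1.23, Fisher's exact test, p = 0.0131). The X share of peaks without RCGTG was 1.09 times that by length (binomial test, exact p = 0.0676).

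Strong peaks beside JmjC histone demethylase genes raised the hypothesis that this family holds peaks more often than other genes. Of 12 members, 5 had a promoter peak (Fisher's exact test, p = 0.00999), but 4 members had been seen before the list was written, so that this p is too small. Among the other 8, 2 had a peak, utx-1 (113) and jmjc-1 (574), an odds ratio of 2.41 (exact p = 0.252), which does not decide the hypothesis. The promoter peaks of jmjd-1.2 (1926), rbr-2 (1502) and jmjd-4, the last being the one at mev-1, held RCGTG, whereas those of utx-1 and jmjc-1 and the peak nearest jmjd-2 did not.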
